A study of Mus musculus with 12 samples.

How the data were processed

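Total RNA from pools of somatic support cells, isolated by flow cytometry from XX and XY gonads at E11.5 and E12.5, was read on Affymetrix Mouse Genome 430 2.0 arrays. Per the labels' protocols the RNA was isolated with a PicoPure kit, amplified in 2 rounds with TargetAmp and labelled with biotin. The 12 arrays fall into 4 groups of 3 pools by the sex and stage that the labels give. The authors deposited 1 table with 1 log2 value per probe set and array. The summarisation, background correction and normalization are not given in the sources used here. The log base is not stated either: the largest value was 14.45, and a 16-bit scanner's range then allows a base of at most 2.15, so values were taken as log2. Such values compress differences near the background, which in XX arrays lay at 3.33 to 5.17 for the 5 Y-linked probe sets that separated the sexes and higher for others. The brightest Sry probe set read up to 7.39 in XX, where signal of the Sry-EGFP reporter of the strain was not excluded. All 12 samples were amplified, which can make probe sets of 1 gene differ.

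The table held 45037 probe sets, of which 798 were blank on every array and 1 on a single array. The remaining 44238 were tested. Gene symbols came from the probe set table supplied with the series and were updated through Entrez identifiers with the RefSeq table of the GRCm38.p6 assembly, which matched 34126 probe sets and was also used for the chromosome of a gene. A single symbol was held by 34328 probe sets, 850 held several and 9060 none, and genes were named only from the first kind. Array medians ran from 6.494 to 6.592. The number of arrays, 3 per group, limits the precision, and no depth applies to arrays.

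Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on 4 group means over all 12 arrays, which share 1 estimate of the spread with 8 residual degrees of freedom and a prior of 2.11 degrees of freedom. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over the 44238 tested, two-sided. Folds are 2 raised to the log2 difference, with 95% intervals from the fit, and the SD between pools is given where n = 3 is named. Each fold is that of 1 probe set, and other probe sets of the gene can differ. All p-values in the text are from limma. The 31 gene lists were tested with camera at a preset correlation between genes of 0.01, with 1 probe set per gene (the brightest on average), and adjusted over the lists of a comparison. With a correlation estimated from the data instead, the lists past the threshold numbered 1, 2, 0, 3 and 2 for sex at E11.5, sex at E12.5, day in XX, day in XY and the interaction, against 11, 12, 11, 11 and 9. Overlaps of calls were set against the product of the numbers called divided by the number tested.

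The groups, comparisons, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. For each comparison the rule takes the 8 largest differences in each direction among called probe sets whose 3 values in 1 group all lie beyond those of the other (no such condition for the interaction), up to 4 members of each list by smallest p, and 15 genes of gonadal development. Y-linked genes, Xist, Tsix, clone names and probe sets with several symbols were left out of the first part. The values of Rock1 on each array, the further probe sets of Atrx, Malat1, Rock1 and Xist and the value of Abcb1a in the interaction were chosen after their values were seen. The values at E12.5 of the Spry4 probe set called at E11.5 were chosen likewise.

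The fit was tested on normal values simulated with each probe set's mean and residual spread (not for the interaction), with 50 probe sets changed at each of 4 sizes. A log2 change of 1 was recovered at 36%, 44%, 42% and 32% of probe sets for sex at E11.5, sex at E12.5, day in XX and day in XY, and one of 3 at 92%, 88%, 88% and 92%. False calls were 7 of 119, 4 of 108, 8 of 121 and 13 of 121. The simulated values had the same spread in all 4 groups and were independent between probe sets. The real residual SD in XX and XY was 0.45 and 0.422 at E11.5 and 0.331 and 0.357 at E12.5. Real pools of E11.5 also differed at many probe sets together. The simulated shares therefore may not hold for the real arrays.

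The alternatives were a filter to the brighter probe sets, quantile normalization, median centring, a variance prior that follows the mean, array quality weights, the pool number as a block, a fit to the compared arrays alone, 1 probe set per gene, a 2-fold minimum, the mean of a gene's probe sets and an estimated correlation for lists, and leaving out each array in turn. A covariate for the difference between E11.5 pools was added after seeing the data: the mean over 365 probe sets that separated XX pool 3 and XY pools 1 and 3 from the other E11.5 pools. Figures were drawn with matplotlib in Python.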

Results

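Gene expression was measured in somatic support cells of the mouse embryonic gonad, the supporting lineage that gives rise to Sertoli cells in the testis and to granulosa cells in the ovary. The cells had been sorted by flow cytometry from XX and XY gonads of a transgenic FVB strain carrying an Sry-EGFP reporter, at embryonic day 11.5 (E11.5) and E12.5. Each of the 4 groups held 3 pools of sorted cells, and each pool was read on 1 Affymetrix mouse array, 12 arrays in all. The study was concerned with genes that act in gonadal sex determination. The design therefore poses 5 comparisons, which are XY against XX at each day, E12.5 against E11.5 in each sex, and the difference between the 2 sex differences. Values are log2 signals per probe set, with array medians from 6.494 to 6.592, and 44238 probe sets were tested, of which 34328 named 1 gene (17996 genes). The labels do not say whether pools came from separate litters, so p-values measure the spread between these pools, part of which may be technical.

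The sex given on each label was read first against Xist, the X-inactivation RNA, and against Y-linked genes. The brightest Xist probe set read 12.8 to 12.95 in the 6 XX arrays and 6.56 to 7.87 in the 6 XY arrays. Eif2s3y, a Y-linked translation factor gene, read at its brightest probe set 3.68 to 4 in XX and 10.85 to 11.36 in XY. Kdm5d and Uty, Y-linked histone demethylase genes, separated the sexes in the same way, Kdm5d with 3.51 to 4.24 against 8.73 to 9.67. No array contradicted its label. At the 5 probe sets of Eif2s3y, Kdm5d and Uty that separated the sexes, XX arrays read 3.33 to 5.17, which is the signal of these probe sets without their target. Others read higher without it, as a further Kdm5d probe set did with 5.43 to 6.04 in XX. Sry read 6.82 to 7.39 in XX, and whether its probe set detects a transcript of the Sry-EGFP reporter was not tested. Where the lower mean of a comparison lay in the range of 3.33 to 5.17, and for Sry, the fold is given as at least that measured. Usp9y and Zfy2, also Y-linked, overlapped between the sexes at 5.58 to 5.92 and 4.75 to 5.15. The 614 X-linked genes and the 17209 autosomal genes had medians of XY minus XX that differed by -0.04 log2 units at E11.5 and by 0.02 at E12.5 (limma camera, adjusted p = 0.26 and 0.82).

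At E11.5 the XY cells already carried the early genes of testis determination. Sry, the Y-linked switch gene, was at least 2.73-fold higher in XY (adjusted p = 0.0067). Sox9, the transcription factor that directs Sertoli fate, was 19.8-fold higher (95% interval 11 to 35.6; log2 means 10.55 ± 0.83 against 6.24 ± 0.56, SD, n = 3). Fgf9, a growth factor of the testis pathway, was 57.1-fold higher (22.9 to 143; adjusted p = 0.0039). Abcb1a, which encodes a multidrug efflux transporter, was at least 39.4-fold higher (adjusted p = 2.6e-05) and was called at both of its probe sets. The other genes higher in XY were Mmd2 (log2 difference 3.08 ± 0.43, SE), Scrn1 (2.50), Phgdh (1.60), which encodes the first enzyme of serine synthesis, Nudt19 (1.25) and Spry4 (1.22), a feedback inhibitor of FGF signalling. The call of Spry4 was at 1 of its 4 probe sets, and its brightest differed by 2.70 and was not called. Rgs4, a regulator of G protein signalling, was at least 9.25-fold lower in XY (adjusted p = 0.02). Lhx9, a LIM homeobox gene of the early gonad, was 3.9-fold lower at 1 of its 4 probe sets and differed by -0.27 ± 0.17 at the brightest, which was not called. Calls were at 1 of 2 probe sets for Sry, Fgf9 and Nudt19, at 1 of 3 for Mmd2, Scrn1 and Rgs4 and at 2 of 3 for Sox9.

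These genes, with Xist, Eif2s3y, Kdm5d and Uty, made up the 15 named genes behind 30 called probe sets, 24 higher and 6 lower in XY; 3012 probe sets had an unadjusted p under 0.05. Of 24 measured genes of the Sertoli differentiation list, Sox9, Fgf9 and Mmd2 were higher, 10 when adjusted over the list alone, and the list's median difference was 0.58 (adjusted p = 8.6e-11, and 0.059 with an estimated correlation). The pregranulosa differentiation list had a median of -0.34 with 0 of 23 genes called (adjusted p = 0.0019, and 0.33 with an estimated correlation), and its call ended without XX E11.5 pool 3 and without XY E11.5 pool 1. Foxl2, a transcription factor of granulosa cells, differed by -0.59 ± 0.28, Fst (follistatin) by -1.43 ± 0.49 and Wnt4 by -0.76 ± 0.35, none of them past the threshold. Amh differed by 0.15 ± 0.30 and Dhh by 1.26 ± 0.45, also not past it. FGF signalling genes had a median of 0.15 with 1 of 17 higher (adjusted p = 0.042, and 0.23 with an estimated correlation). The gonadal regulators Gata4 (0.78 ± 0.33), Wt1 (0.67 ± 0.21) and Nr5a1 (0.94 ± 0.30) were not called.

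Genes of other cell types and of the cell cycle stood lower in XY at E11.5 as lists, without a called member. The medians were -0.55 for 18 endothelial markers, -0.57 for 15 macrophage and leukocyte markers, -0.53 for 15 interstitial mesenchyme markers and -0.59 for 26 cell cycle genes (adjusted p = 1.1e-05, 1.3e-06, 0.0012 and 4e-05; with an estimated correlation, adjusted p = 0.48, 0.29, 0.48 and 0.53). Pool 2 of XX E11.5 stood apart on these lists: its endothelial markers lay 1.92 log2 units above their 12-array means, its mesenchyme markers 1.32, its cell cycle genes 1.28 and its macrophage markers 0.94. Without that pool the medians of the endothelial, mesenchyme and cell cycle lists were -0.01, 0.05 and 0.01 and their calls ended. Cell cycle inhibitors (median -0.35), X-linked escape genes (-0.26) and X-inactivation RNAs (-0.30) were also lower as lists, with an adjusted p of 0.11, 0.18 and 0.11 with an estimated correlation. The Y-linked list (4 of 7 genes higher) kept its call with an estimated correlation (adjusted p = 0.0026). Of the 15 named genes 9 kept their call without any 1 of the 12 arrays, whereas those of Mmd2, Phgdh, Nudt19, Spry4, Rgs4 and Lhx9 each ended without XX E11.5 pool 2, without XY E11.5 pool 2 and without at least 1 further array. That of Mmd2 (adjusted p = 0.041) ended without each array but XX E11.5 pool 1 and XY E11.5 pool 3. Phgdh (adjusted p = 0.041) lost its call without each array but XY E11.5 pool 3 and XY E12.5 pool 2. The calls of Nudt19 and Spry4 also ended without XX E11.5 pool 1, without XY E11.5 pool 1 and without several E12.5 pools in turn. The count of 30 was 57 without XY E11.5 pool 3 and 12 both with the E11.5 arrays alone in the fit and with 1 probe set per gene.

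**Figure D1:**
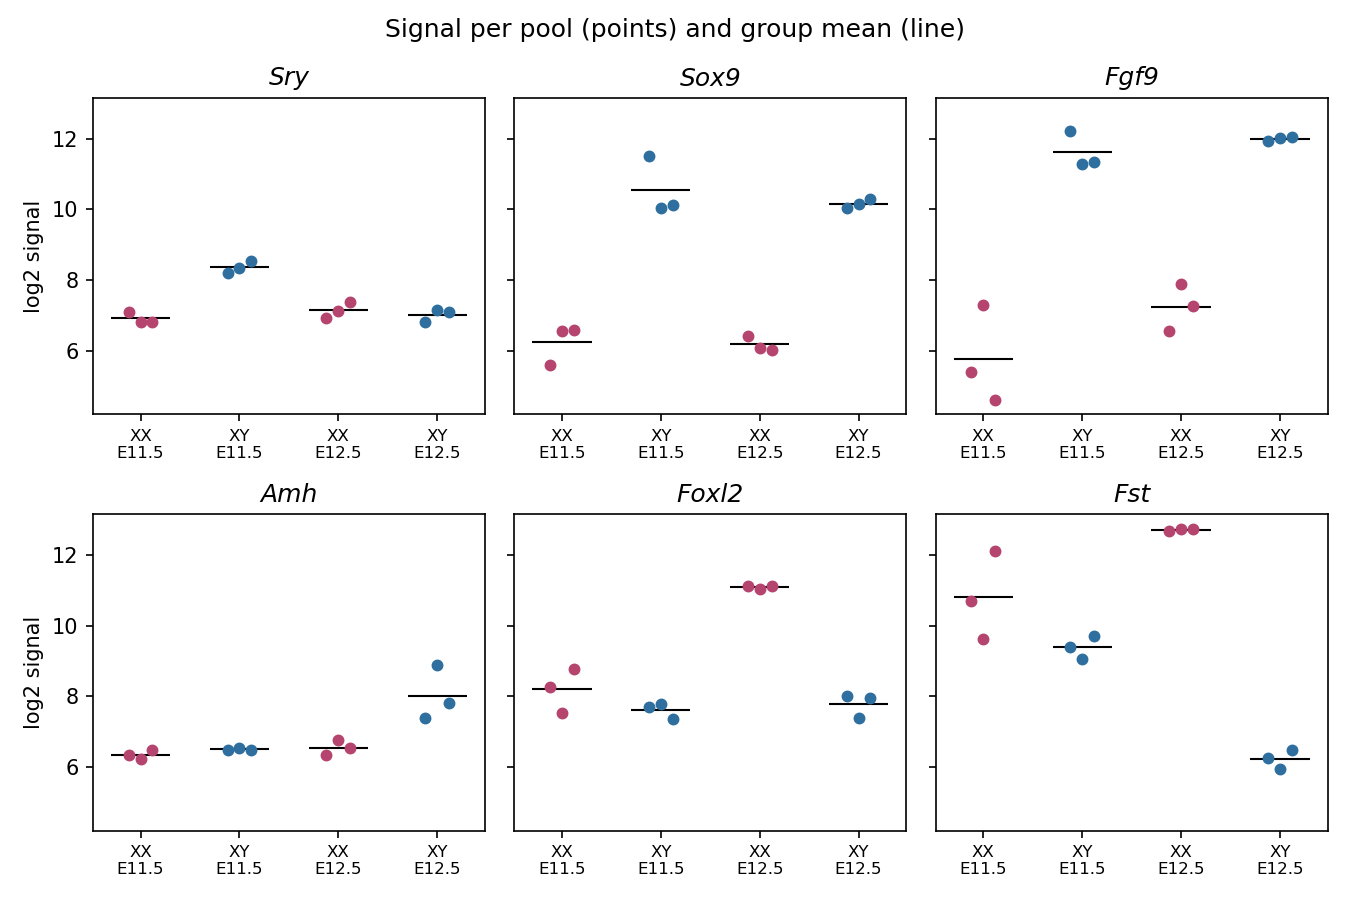
Log2 signal of 6 genes on each array at the brightest probe set, with the 3 pools of each group as points, the group mean as a line and 1 panel per gene. Sox9 and Fgf9 separated XY from XX at both days, Sry was higher in XY at E11.5 and not at E12.5, and Foxl2 was higher in XX at E12.5.

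One day later the sexes had parted on a broad front, with 3416 probe sets called, 1732 higher and 1684 lower in XY (2507 named genes). Sertoli genes were high in XY. Of the 24 measured members of that list 20 were higher and 0 lower (median difference 3.19; adjusted p = 1.3e-22, and 0.011 with an estimated correlation). They included Dhh, the desert hedgehog ligand (45.2-fold, 95% interval 22.6 to 90.4), Ptgds, which makes prostaglandin D2 (55.8-fold, 33.1 to 94), Col9a3, a collagen IX chain (144-fold, 45.3 to 455), Cbln4 (31.7-fold), Sox9 (15.8-fold) and Fgf9 (26.9-fold). Amh, the hormone that removes the Müllerian duct, was 2.78-fold higher (1.74 to 4.43; adjusted p = 0.015). Outside the lists, and with clone names left out, the largest measured differences in this direction were at Ppargc1a, a coactivator of mitochondrial genes (at least 66-fold), Gdnf, a growth factor for germline stem cells (57.9-fold), Col14a1, the kinase gene Pak3 (45-fold) and Afap1l2. All probe sets were called for Dhh, Ptgds, Col9a3, Sox9, Fgf9 and Afap1l2, against 3 of 5 for Ppargc1a, 3 of 4 for Pak3 and 1 of 2 for Col14a1.

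Pregranulosa genes were low in XY at E12.5, where 18 of 23 were lower and 0 higher (median -2.62; adjusted p = 2.2e-19, and 0.012 with an estimated correlation). Fst was 90.3-fold lower (95% interval 42.7 to 191), Rspo1, a WNT potentiator of the ovary, 15.6-fold (9.6 to 25.2), Foxl2 9.83-fold (6.35 to 15.2), Gng13 12.7-fold, Bmp2 8.43-fold and Wnt4 4.74-fold. Axin2 (-1.86 ± 0.14) and Lef1 (-2.66 ± 0.42), which respond to beta-catenin, were also lower, but the wider list of WNT targets had 2 genes higher and 3 lower (adjusted p = 0.82). Outside the lists, and with Xist and clone names left out, the largest measured differences in this direction were at Slitrk1 (96.2-fold, 44.5 to 208), which encodes a synaptic adhesion protein, Cd244a (at least 41.7-fold), Dclk1 (40.9-fold), a doublecortin-like kinase gene, Tph2 (at least 40.7-fold), which encodes an enzyme of serotonin synthesis, Sphkap (40.2-fold), Ccdc182 (37.2-fold) and Vav3 (37-fold). Among early gonad regulators Lhx9 was 17.6-fold lower (13.5 to 22.7), Emx2 8.94-fold and Nr0b1 2.91-fold, whereas Gata4 (0.01 ± 0.33), Nr5a1 (0.23 ± 0.30) and Wt1 (-0.05 ± 0.21) were not called. Sry no longer differed past the threshold (-0.13 ± 0.16). Of the genes lower in XY, Foxl2, Gng13, Axin2, Lef1, Sphkap and Cd244a were called at 1 of 2 probe sets. Fst, Wnt4 and Ccdc182 were called at 2 of 2, Vav3 at 2 of 3, Lhx9 at 3 of 4 and Dclk1 at 5 of 9.

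Signalling genes were called in both directions at E12.5. In the Notch list 4 of 16 genes were higher in XY, 9 when adjusted over the list alone, and 0 lower (median 0.91; adjusted p = 4e-06, and 0.057 with an estimated correlation): the target genes Hes5 (9.36-fold), Hey2 (at least 4.57-fold) and Heyl (2.36-fold) and the ligand gene Jag1 (4.95-fold). In the FGF signalling list 5 of 17 genes were higher in XY and 1 lower (median 0.62; adjusted p = 0.014, and 0.1 with an estimated correlation): Spry4 was 19.7-fold and Etv5 43.4-fold higher, and the receptor gene Fgfr2 7.06-fold lower. The fold of Spry4 is that of its brightest probe set. The Spry4 probe set called at E11.5 had log2 means of 6.77 in XX and 7.99 in XY at E12.5. Ptch1, a hedgehog receptor that the pathway also induces, was 4.5-fold higher, while the hedgehog coreceptor genes Gas1 and Boc were 2.66-fold and 4.81-fold lower (list adjusted p = 0.22). Cyp26b1, which degrades retinoic acid, was 4.34-fold higher, and Dhrs3, a retinaldehyde reductase gene, 5.88-fold lower (list adjusted p = 0.89). Of the gap and tight junction genes Gjb2 (connexin 26) was 28.2-fold higher (list adjusted p = 0.18). In the migration and guidance list Robo1 was 14.3-fold higher and Sema3a and Nrp1 were 9.15-fold and 8.66-fold lower (list adjusted p = 0.89). Heyl, Fgfr2, Ptch1 and Robo1 were called at 1 of 3 probe sets, Hes5 at 1 of 2 and Nrp1 at 2 of 4. Jag1, Etv5, Gas1, Boc and Sema3a were called at 2 of 3 and Spry4 at 3 of 4.

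Cell cycle genes ran higher in XY at E12.5 (median 1.34; 5 of 26 called, 14 when adjusted over the list alone; adjusted p = 3.5e-06, and 0.49 with an estimated correlation). The called genes included the mitotic kinase genes Aurka (4.33-fold) and Cdk1 (4.67-fold), Bub1 (10-fold) and Nusap1 (5.34-fold). The inhibitor genes Cdkn1c (5.18-fold), Cdkn1b (2.75-fold) and Cdkn1a (5.67-fold) were lower in XY (list adjusted p = 0.82). Cell cycle genes lay -1.24, -0.32 and -0.43 from their 12-array means in the 3 XX E12.5 pools and 0.69, 0.51 and 0.80 in the 3 XY E12.5 pools. Imprinted genes were lower in XY (9 of 18 called, median -0.69; adjusted p = 6.9e-05, and 0.057 with an estimated correlation), with Zim1 13.1-fold and Slc38a4 2.83-fold lower, and Cdkn1c belongs to this list too. Immediate early genes were higher (5 of 19, median 0.94; adjusted p = 0.00054, and 0.42 with an estimated correlation), among them Egr1 (2.82-fold), Junb (1.92-fold) and Dusp1 (3.09-fold). The hypoxia list split, with Adm (-3.86 ± 0.32) and Ndrg1 (10.1-fold) lower and P4ha1 3.32-fold higher (adjusted p = 0.87). Aurka, Bub1, Nusap1, Cdkn1b, Cdkn1a, Slc38a4 and P4ha1 were called at 1 of 2 probe sets, Adm at 2 of 2 and Ndrg1 at 3 of 5.

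Few markers of other cells were called between the sexes at E12.5. No germ cell, endothelial or steroidogenic marker was called (0 of 18, 0 of 18 and 0 of 9), and Pou5f1, a germ cell transcription factor, read 5.96 ± 0.23 in XX and 5.89 ± 0.13 in XY (SD, n = 3). Klf1 was the called member of 9 erythroid markers (2.68-fold higher), and Ptch1 and Pdgfra (3.62-fold) were the called members of 15 mesenchyme markers, each at 1 of 3 probe sets. Macrophage markers (0 of 15 called, median 0.41), ribosomal proteins (0 of 17, -0.22) and mesonephric markers (1 of 14, Emx2) passed as lists, with an adjusted p of 0.72, 0.59 and 0.42 with an estimated correlation. Jpx, a neighbour of Xist, was 2.29-fold lower in XY at 1 of its 2 probe sets. The X-inactivation and Y-linked lists had an adjusted p of 0.057 and 0.051 with an estimated correlation. The calls of Amh, Heyl, Cdk1, Bub1, Nusap1, Egr1, Junb, Dusp1, Klf1, Pdgfra and Jpx at E12.5 ended without XX E12.5 pool 3, and each also without at least 1 other array. That of Nusap1 (adjusted p = 0.047) ended without each array but XX E11.5 pools 2 and 3. Cdk1 and Dusp1 lost theirs without any 1 of the XY E12.5 pools, and Bub1 also without pool 1 of each group. The calls of Afap1l2 and Jag1 ended without XX E12.5 pool 1 and without XY E12.5 pool 3, and that of Jag1 also without XX E12.5 pool 2. The count of 3416 was 2054 without XX E12.5 pool 3, 2089 without XY E12.5 pool 3 and 5794 with array quality weights.

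**Figure D2:**
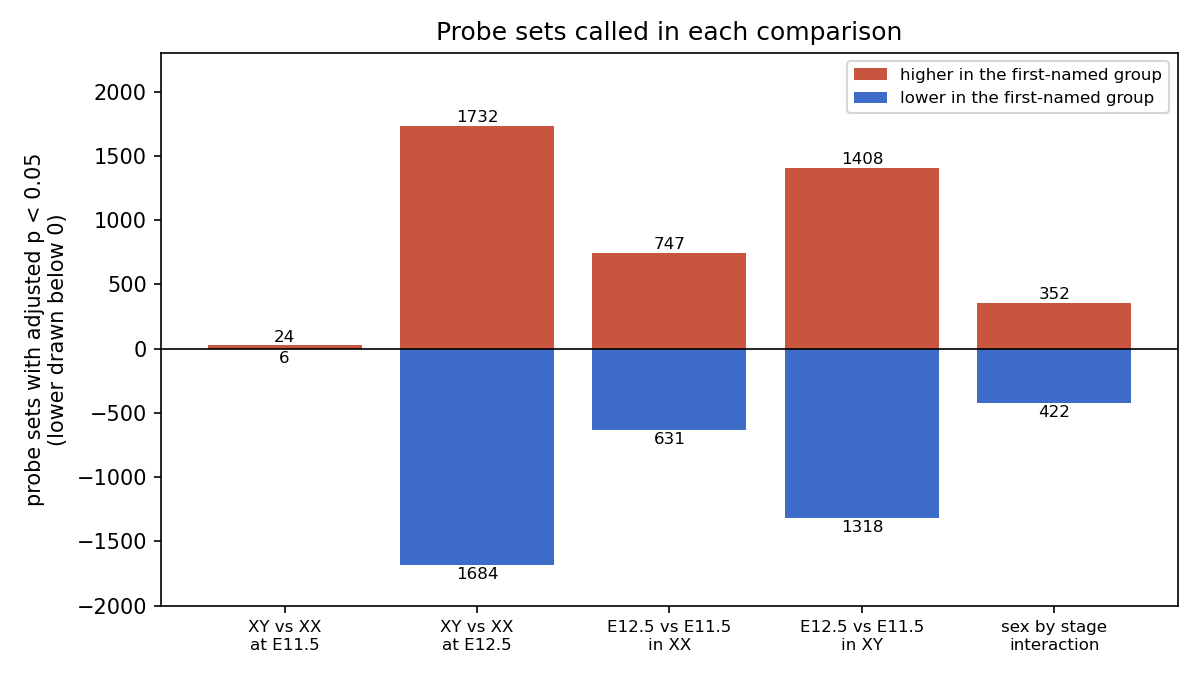
Number of probe sets with an adjusted p under 0.05 in each of the 5 comparisons, with bars above 0 for probe sets higher in the first-named group and bars below 0 for those lower. The bars run from 24 higher and 6 lower for sex at E11.5 to 1732 higher and 1684 lower for sex at E12.5.

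In XX cells 747 probe sets rose and 631 fell from E11.5 to E12.5 (1058 named genes). Ovarian genes rose. Of 23 pregranulosa genes 9 rose and 1 fell (median 0.83; adjusted p = 4.7e-05, and 0.31 with an estimated correlation), and they included Gng13 (10.2-fold, 95% interval 6.6 to 15.7), Foxl2 (7.42-fold, 4.79 to 11.5), Rspo1 (5.01-fold), Axin2 (2.74-fold) and the Iroquois genes Irx3 and Irx5 (10.1-fold and 11.9-fold). The leading genes outside that list were Egfl6 (14.2-fold), the calcium channel gene Cacna1d (11.7-fold), Irs4 (9.88-fold), Stum and Insyn2b. Fst differed by 1.91 ± 0.49 and was not called (adjusted p = 0.063). Of the Sertoli list Cbln4 fell 16.1-fold and Cyp26b1 3.23-fold, with a list median of -0.06 (adjusted p = 0.022, and 0.51 with an estimated correlation). Robo1 fell 15.3-fold, Pdgfc 3.04-fold and Sema3c 3.52-fold in the guidance list (median -0.54; adjusted p = 0.00016, and 0.30 with an estimated correlation), and Hapln1, a link protein gene of the matrix, fell at all 4 of its probe sets, 17-fold at the one that changed most.

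Cell cycle genes had a median change of -0.81 in XX with 0 of 26 called (adjusted p = 4e-07, and 0.51 with an estimated correlation), and -0.31 without XX E11.5 pool 2. Endothelial markers (median -0.51), macrophage markers (-0.07) and mesenchyme markers (-0.26), all high in that pool, were lower as lists with an adjusted p of 0.60, 0.60 and 0.51 with an estimated correlation, and these 3 calls ended without it, where the endothelial median was 0.20. Pdgfra and Nr2f2, mesenchyme genes, fell 4-fold and 3.23-fold, and both calls ended without XX E11.5 pool 2 and also without XX E11.5 pool 3. Glycolysis genes (0 of 17 called, median -0.34), hypoxia genes (0 of 16, -0.35) and cholesterol biosynthesis genes (1 rose and 3 fell of 18, -0.11) were lower and ribosomal protein genes higher (1 of 17, 0.40) as lists, with an adjusted p of 0.43, 0.31, 0.51 and 0.60 with an estimated correlation. Without XX E12.5 pool 3 the calls in XX of Irx3, Insyn2b, Cyp26b1, Pdgfc, Sema3c, Pdgfra and Nr2f2 ended, all but that of Irx3 also without pool 2. Those of Insyn2b and Sema3c also ended without XX E11.5 pool 2, and those of Cyp26b1 and Sema3c without XX E11.5 pool 3. The count of 1378 was 183 without XX E12.5 pool 3, 218 without XX E12.5 pool 2, 593 and 596 without XX E11.5 pools 2 and 3, 909 without XY E12.5 pool 3, 624 with the XX arrays alone, 2405 with array quality weights and, in a fit chosen after seeing the data, 164 with a per-array measure of the difference between E11.5 pools as a covariate, which ended the calls of 9 of the 26 genes named in XX: Rspo1, Cyp26b1, Pdgfc, Sema3c, Pdgfra, Nr2f2, Atrx, Rock1 and Cyp11a1.

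In XY cells 1408 probe sets rose and 1318 fell over the day (1917 named genes). Sertoli genes rose. Of 24 members 13 rose and 0 fell (median 1.08; adjusted p = 1.9e-10, and 0.048 with an estimated correlation), led by Ptgds (52.9-fold, 95% interval 31.4 to 89), Defb19, a defensin gene (39.9-fold, 27.4 to 58), Col9a3 (30-fold), Gstm6 (13-fold) and Dhh (18.4-fold, 9.21 to 36.9), with Amh 2.86-fold. For Amh this fold too is a minimum if its reading at E11.5 is background. Sox9 (-0.39 ± 0.38) and Fgf9 (0.38 ± 0.59) were not called, and Sry fell at least 2.54-fold (adjusted p = 0.0011) to a level no higher than in XX (7.01 and 7.14). Pregranulosa genes fell (9 of 23, median -1.20; adjusted p = 1.6e-10, and 0.048 with an estimated correlation), with Fst down 8.94-fold, Fgfr2 3.02-fold, Sprr2d 10.4-fold and Rspo1 2.45-fold. Early gonad regulators fell (6 of 18, median -0.13; adjusted p = 0.00016, and 0.048 with an estimated correlation), with Lhx9 down 14.2-fold (10.9 to 18.4) and Emx2 8.67-fold. Among the largest rises outside these lists were Afap1l2 (40.6-fold), Nell1 (37.7-fold), Tmcc3 (35-fold), Erbb3, a neuregulin receptor gene (33.5-fold), and Rerg (at least 28.5-fold). Sphkap (80.4-fold), the calcium buffer gene Calb1 (78.5-fold) and Slitrk1 (54.7-fold) were among the largest falls.

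Notch genes rose in XY (6 of 16, median 0.53; adjusted p = 0.00094, and 0.17 with an estimated correlation), with Jag1 up 12.9-fold, Hes5 6.75-fold and Hey2 at least 4.29-fold. Gjb2 rose 17.2-fold and Cldn11, a tight junction gene, 9.42-fold (list adjusted p = 0.34). Imprinted genes fell (5 of 18, median -0.14; adjusted p = 0.00018, and 0.088 with an estimated correlation), Zim1 by 14.3-fold and Cdkn1c by 5.27-fold. Adm fell 7.2-fold and Ndrg1 6.37-fold in the hypoxia list (4 of 16, median -0.22; adjusted p = 0.00048, and 0.11 with an estimated correlation). Junb rose 2.91-fold and Egr1 3.58-fold (immediate early list, median 0.62; adjusted p = 0.011, and 0.48 with an estimated correlation), and Aurka rose 3.15-fold (cell cycle list, median 0.93; adjusted p = 0.00094, and 0.60 with an estimated correlation). Macrophage markers were higher as a list (median 1.03; Cd68 called, 2.52-fold), and glycolysis and guidance genes lower (-0.28 and -0.01), with an adjusted p of 0.43, 0.35 and 0.19 with an estimated correlation. Cyp11a1, which makes the first steroid of the steroidogenic pathway, fell 16.1-fold in XY (8.58 to 30.1) and 5.88-fold in XX (3.14 to 11) at 1 of its 3 probe sets. The count of 2726 was 1277 without XY E11.5 pool 3, 1369 without XY E12.5 pool 3, 1660 without XY E12.5 pool 2, 1430 with 1 probe set per gene and 499 with the covariate for the difference between E11.5 pools, which ended the calls of 16 of the 40 genes named in XY: Col9a3, Amh, Fst, Rspo1, Afap1l2, Nell1, Tmcc3, Jag1, Hey2, Cldn11, Junb, Aurka, Cd68, Rbm5, Wnk1 and Atrx. The calls of Amh, Rspo1, Afap1l2 and Cd68 in XY ended without XY E11.5 pool 3, and of these Amh alone kept its call without each other array. That of Cd68 (adjusted p = 0.049) ended without each array but XX E11.5 pool 3, XY E11.5 pool 2 and XY E12.5 pool 1. Rspo1 also lost its call without any 1 of the XX E12.5 pools and without further arrays, and Afap1l2 without any 1 of the XY E12.5 pools. The call of Aurka in XY ended without XY E11.5 pool 1, XY E12.5 pool 2 or XY E12.5 pool 3.

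Many of the largest falls over the day were at some probe sets of a gene and not at others. Akap9 (at least 30-fold in XX), Atrx (28.7-fold), Malat1 (26.5-fold), a nuclear noncoding RNA, Rock1 (at least 22.5-fold), Zfp292 (at least 18-fold) and the mitotic motor gene Cenpe (at least 30.7-fold) fell in XX, and Rbm5 (at least 65.7-fold), Wnk1 (54.4-fold), Atrx (54.4-fold), Malat1 (at least 44.8-fold) and Resf1 (47.6-fold) in XY. Resf1 fell in XY at all 4 of its probe sets. At the brightest probe set of Atrx the change was -0.48 in XX and 0.31 in XY, and at that of Malat1 it was -0.02 and -0.43, none of them called. Rock1 changed downward at every probe set, at the brightest by -1.83 in XX, not called, and by -2.48 in XY (adjusted p = 0.014). Without XX E12.5 pool 3 the calls in XX of Cenpe, Atrx, Malat1, Rock1, Zfp292 and Cyp11a1 ended, as they did without pool 2. Those of Atrx and Rock1 in XX also ended without XX E11.5 pool 2, without XX E11.5 pool 3 and without any 1 of the XY E12.5 pools. Xist showed the contrast of Atrx and Malat1 in XX, where 1 probe set fell by 5.03 (adjusted p = 0.026) while the brightest changed by 0.07. Over the 152 named genes that fell in both sexes, 130 had another probe set with a group mean of at least 8; the fallen probe sets had a median change of -1.95 and the others -0.28. For genes that rose in both sexes the medians were 1.24 and 0.88, over 28 genes. Some of these probe sets also differed between pools of 1 day: that of Rock1 read 11.22, 11.19 and 10.15 in XX pool 3 and XY pools 1 and 3 of E11.5, and 7.22, 9.20 and 7.72 in XX pools 1 and 2 and XY pool 2.

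**Figure D3:**
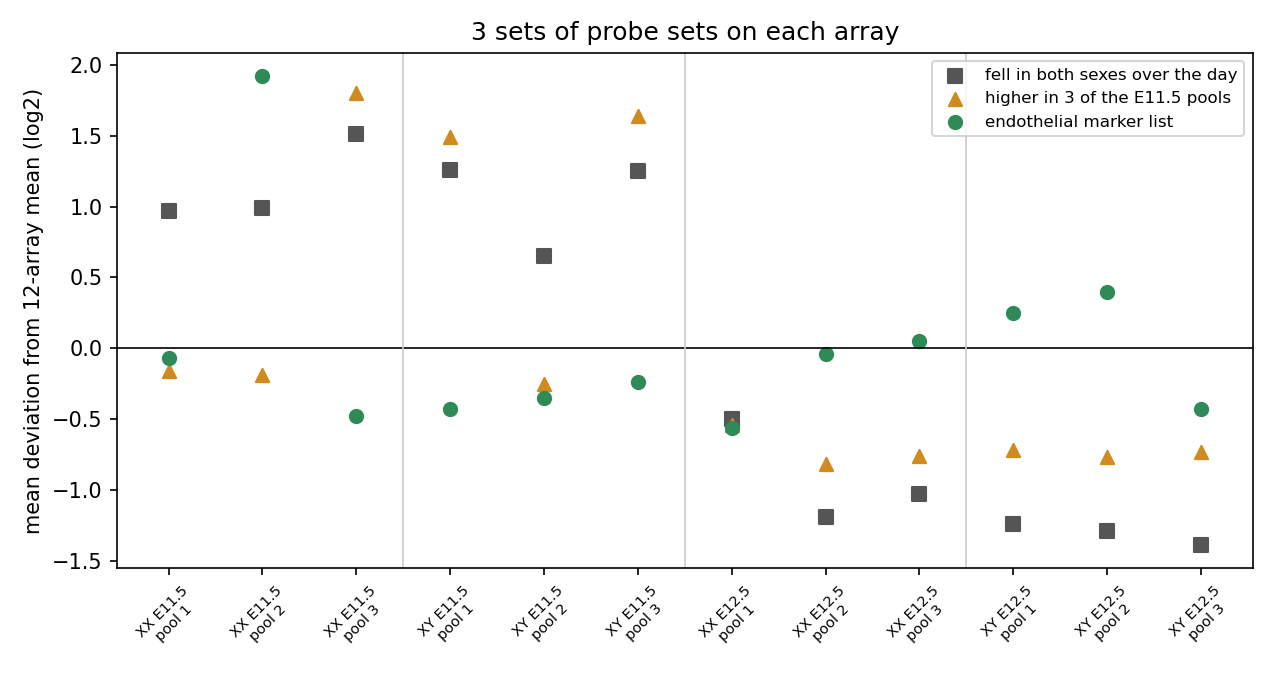
Mean deviation from the 12-array mean (log2 units) on each array for 3 sets, which are the 213 probe sets that fell in both sexes, the 365 probe sets higher in XX pool 3 and XY pools 1 and 3 of E11.5 than in the other E11.5 pools, and the endothelial marker list. The first set is above 0 on all 6 E11.5 arrays (0.65 to 1.51), the second is at 1.49 to 1.80 on 3 of them, and the third reaches 1.92 in XX E11.5 pool 2.

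The change over the day differed between the sexes at 774 probe sets (638 named genes), 352 with the XY minus XX difference moving up and 422 with it moving down. Sertoli genes moved up (10 of 24, median 1.62; adjusted p = 1.6e-15, and 0.021 with an estimated correlation), as Ptgds (log2 difference of differences 5.10 ± 0.48, SE), Cbln4 (4.60 ± 0.46), Defb19 (4.39 ± 0.34) and Dhh (4.24 ± 0.64) showed. Pregranulosa genes moved down (12 of 23, median -2.29; adjusted p = 4.2e-16, and 0.021 with an estimated correlation), with Fst at -5.07 ± 0.69, Rspo1 at -3.62 ± 0.44, Gng13 at -3.62 ± 0.40 and Foxl2 at -2.71 ± 0.40. Other genes moving up were Pak3 (5.93), Erbb3 (5.12), Robo1 (4.18) and Gjb2 (4.07), and by at least the measured value Pcdh8 (5.66), a protocadherin gene, and Ms4a6d (4.68). Those moving down were Slitrk1 (-6.34), Vav3 (-5.32), Sphkap (-5.25), Dclk1 (-5.17), Sema3a (-4.02), Lhx9 (-3.86), Zim1 (-3.67) and Ndrg1 (-3.63), and by at least the measured value Tph2 (-6.00), Taf7l (-5.18) and Cd244a (-5.18). Epyc (4.83), Rtn4rl1 (4.74), Rerg (4.72), Abcb1a (-4.88) and Sry (-1.57) were also called, but means at or near background enter their values with both signs, so the size of these changes is bounded on neither side. Sox9 (-0.33 ± 0.54), Fgf9 (-1.09 ± 0.84), Amh (1.32 ± 0.43) and Wnt4 (-1.48 ± 0.50) were not called.

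As lists, cell cycle genes (median 2.14, 1 of 26 called), Notch genes (0.78, 3 of 16), endothelial markers (1.06, 0 of 18), macrophage markers (0.92, 0 of 15) and immediate early genes (0.67, 0 of 19) moved up, with an adjusted p of 0.40, 0.18, 0.60, 0.39 and 0.45 with an estimated correlation. The endothelial call ended without XX E11.5 pool 2, and the cell cycle median was then 1.38. Imprinted genes (-0.54, 2 of 18) and ribosomal protein genes (-0.35, 0 of 17) moved down, with an adjusted p of 0.18 and 0.59 with an estimated correlation. The count of 774 ranged from 403 without XX E12.5 pool 3 to 1273 without XY E11.5 pool 1, and it was 442 and 501 without XY E11.5 pools 2 and 3, 489 without XX E12.5 pool 2 and 480 without XY E12.5 pool 3. The call of Pak3 ended without XX E12.5 pool 3 and that of Pcdh8 without 7 of the 12 arrays in turn.

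Of the 30 probe sets called for sex at E11.5, 20 were also called at E12.5 in the same direction, 17 higher and 3 lower (0.94 and 0.228 expected from the numbers called), and 0 in the opposite direction. They named Fgf9, Lhx9, Mmd2, Nudt19, Scrn1, Sox9, Spry4, Xist, Eif2s3y, Kdm5d and Uty. The shared calls of Xist, Eif2s3y, Kdm5d and Uty follow from the sex chromosomes. The expected counts leave this aside, and also that a gene can hold several called probe sets. Abcb1a, Phgdh, Rgs4 and Sry were called at E11.5 and not at E12.5. Of these, Abcb1a and Sry passed the interaction test and Phgdh and Rgs4 did not. Across all probe sets, which are not independent replicates, the 2 sex differences correlated with Pearson's r = 0.13. The count of 20 was 43 without XY E11.5 pool 3 and 9 with 1 probe set per gene. Over the day 101 probe sets rose in both sexes and 213 fell in both (23.8 and 18.8 expected), 40 moved in opposite directions (42.3 expected), and the correlation was 0.38. With 1 probe set per gene the shared counts were 91 rising and 62 falling, and the total of 314 was 43 without XX E12.5 pool 3, 49 without XX E12.5 pool 2, 131 and 184 without XX E11.5 pools 3 and 2, 196 without XY E11.5 pool 3, 205, 198 and 151 without XY E12.5 pools 1, 2 and 3, 539 with array quality weights and 26 with the covariate for the difference between E11.5 pools.

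**Figure D4:**
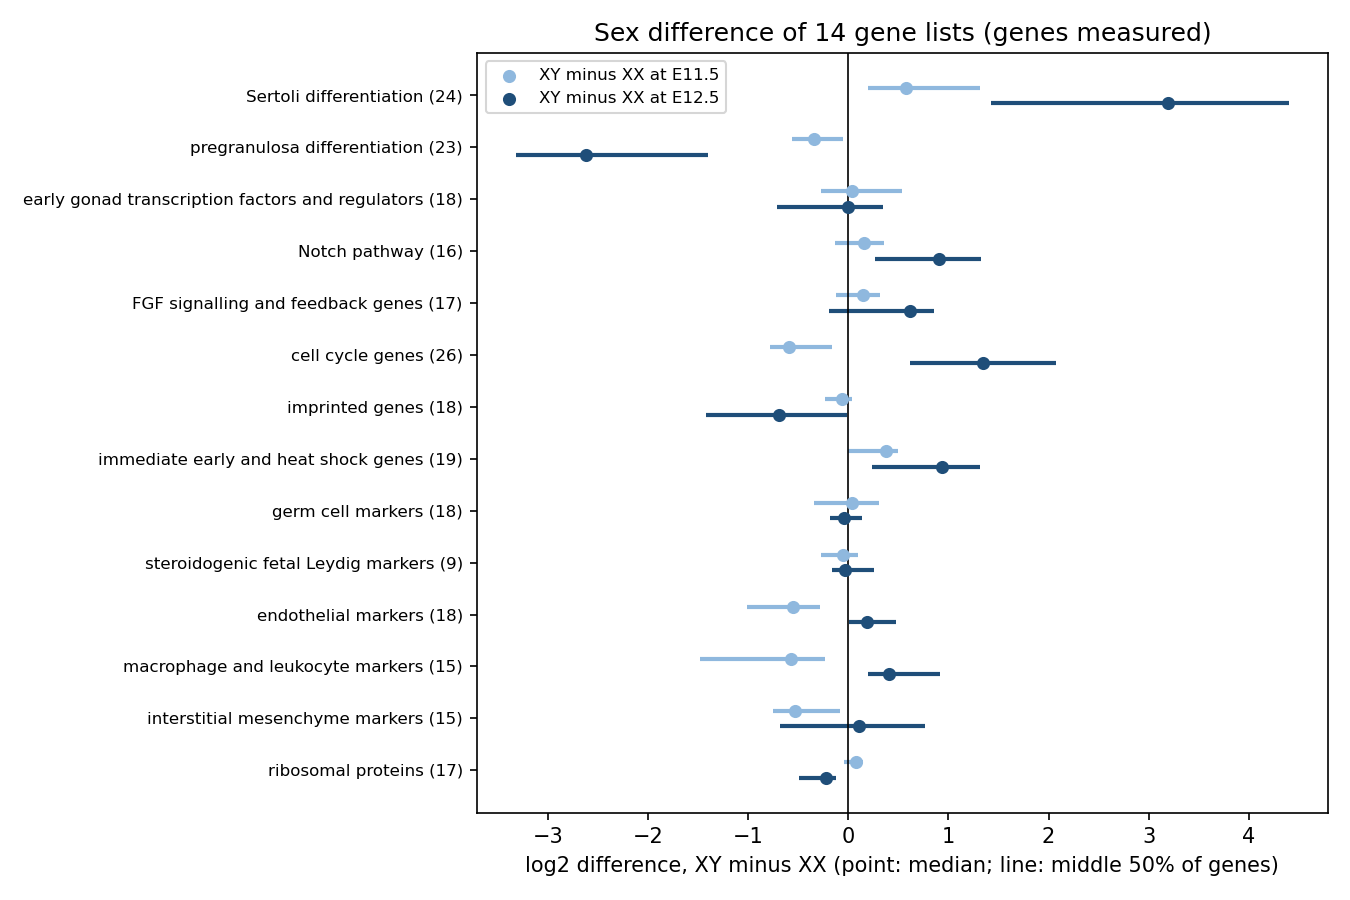
Median log2 difference (point) and middle 50% of members (line) of 14 gene lists for XY minus XX at E11.5 and at E12.5. Sertoli genes moved from 0.58 to 3.19 and pregranulosa genes from -0.34 to -2.62.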

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

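The interaction test, the list tests and the leaving out of arrays were planned, and the second list of endothelial genes was set before its values were seen; the other tests of explanations, the splits of the samples and the covariate were chosen after the results were seen.

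The sex difference changed between the days, by the interaction test, at 52 of the genes named above. The change was upward for Pak3 (5.93), Erbb3 (5.12), Ptgds (5.10), Cbln4 (4.60), Defb19 (4.39), Dhh (4.24), Robo1 (4.18), Gjb2 (4.07), Gstm6 (3.34), Jag1 (3.33), Hes5 (2.80), Aurka (2.75) and Ptch1 (2.14), and by at least the measured value for Pcdh8 (5.66) and Ms4a6d (4.68). Among genes of the ovarian pathway and of the early gonad it was downward for Fst (-5.07), Sprr2d (-4.34), Irx3 (-3.86), Lhx9 (-3.86), Irx5 (-3.64), Rspo1 (-3.62), Gng13 (-3.62), Emx2 (-3.00), Foxl2 (-2.71), Bmp2 (-2.40), Nr0b1 (-2.29), Fgfr2 (-2.27) and Axin2 (-1.59). It was also downward for Slitrk1 (-6.34), Vav3 (-5.32), Sphkap (-5.25), Dclk1 (-5.17), Ccdc182 (-4.89), Calb1 (-4.26), Sema3a (-4.02), Zim1 (-3.67), Ndrg1 (-3.63), Adm (-3.16), Stum (-3.15), Cacna1d (-3.13), Dhrs3 (-2.26) and Cdkn1c (-2.18), and by at least the measured value for Tph2 (-6.00), Taf7l (-5.18) and Cd244a (-5.18). For Epyc (4.83), Rtn4rl1 (4.74), Rerg (4.72), Hey2 (2.47), Abcb1a (-4.88), Irs4 (-3.22) and Sry (-1.57) means at or near background enter with both signs, so the size is bounded on neither side. Of the lists, the median change was 1.62 for Sertoli genes, -2.29 for pregranulosa genes, 2.14 for cell cycle genes, 1.06 for endothelial markers, 0.92 for macrophage markers, 0.78 for Notch genes, 0.67 for immediate early genes, -0.54 for imprinted genes and -0.35 for ribosomal proteins. With an estimated correlation the Sertoli and pregranulosa lists kept their calls (adjusted p = 0.021 for both) and the other 7 lost them, in that order with an adjusted p of 0.40, 0.60, 0.39, 0.18, 0.45, 0.18 and 0.59; the endothelial call also ended without XX E11.5 pool 2, at a median of 0.22.

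Of 100 drawn splits that exchanged sexes within each day, 10, the real one included, called at least the real 774 probe sets in the interaction. The 9 others that kept the E12.5 pools grouped by sex, with the XX and XY labels in place or exchanged as a whole, called 1074 to 2397. Those with the E12.5 labels in place called 1539 and 1158. The split with the real E11.5 groups and exchanged E12.5 labels, which tests the sum of the 2 sex differences, called 1747. The 90 that mixed the sexes at E12.5 called at most 71. The former keep the size of the E12.5 sex difference and the latter remove it by construction. The 10 splits that keep the E12.5 groups, the real one included, are too few for a share under 0.05. For lists 19 of 100, the real one included, reached the real 9, with 11 the highest, and chance is not excluded. For sex at E11.5 the real count was 30 and the highest other split, XX pool 3 with XY pools 1 and 3 against the rest, gave 401, which points to a structure of the samples; 3 of the 10 splits reached 30. The 10 splits of each single comparison are too few for a share under 0.05. The real and highest other counts were 3416 and 0 for sex at E12.5 (1 split as large, the real one), 1378 and 1 for the day in XX, 2726 and 1 for the day in XY, and for lists 11 and 8, 12 and 8, 11 and 11 (2 splits) and 11 and 7 in the same order. For the 2 overlaps the real pair was the 1 pair of 100 as large, with same-direction counts of 20 against 7 and 314 against 0. Only 5 and 6 of the 100 pairs had calls in both comparisons, without which no overlap can arise, so these counts are too few for a share under 0.05.

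The 1st pattern was the fall over the day in both sexes at some probe sets of a gene and less at others, as at Atrx and Malat1. Rock1 was a mixed case, since all its probe sets changed downward, the brightest by -1.83 in XX and by -2.48 in XY. The other probe sets of the genes that fell in both sexes moved 0.14 as far at the median, against 0.16 for falls called in XY alone, 0.35 for those in XX alone, 0.38 and 0.37 for genes lower and higher in XY at E12.5, and 0.71 for shared rises. Taking the called probe set lowers such a ratio by itself, so a fall of the whole transcript stays open. With the covariate for the difference between E11.5 pools 20 probe sets fell in both sexes, against 213 without it (Atrx in XY went from -5.77 to -3.16 and Malat1 in XY from -5.48 to -3.69, the latter still called), but the covariate also goes with the day. In a 3rd test of pools, chosen after the 2 before it were seen, the 3 E11.5 pools low on the covariate were read on all probe sets called as falling in the other sex. They lay above the highest E12.5 array of their sex by 0.25 (XX pool 2, SD of the E12.5 arrays 0.21), 0.46 (XX pool 1, 0.21) and 0.63 (XY pool 2, 0.08). These probe sets were not limited to the genes of this pattern, and other falls over the day would give such gaps too. The test therefore cannot decide whether pools caused the pattern, in whole or in part. A processing difference that goes with the day also stays open. Shorter amplified RNA and another transcript form cannot be told apart, because both leave some probe sets unchanged, and 26.2% of the genes had others that moved at least 50% as far.

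The 2nd pattern was the high level of endothelial, mesenchyme and cell cycle genes in XX E11.5 pool 2. A brighter array was not tested by its median of 6.521, because all 12 medians lay within 6.494 to 6.592, as values scaled to a common level do. Of 20 genes of a second endothelial list 15 were highest in that pool, as were 17 of 18 of the first list, and among the brightest were Aplnr 13.04 (12.02 on the next array), Cd93 10.3 (8.73), Kdr 10.24 (8.82) and Tek 10.23 (7.88). These values are consistent with endothelial cells in the pool despite the sort. Also highest there were 10 of 15 mesenchyme, 6 of 15 macrophage, 3 of 9 steroidogenic, 3 of 14 mesonephric, 1 of 9 erythroid and 2 of 18 germ cell markers and 19 of 26 cell cycle genes; whether further cell types were present, and whether the embryos of that pool differed, was not tested.

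The 3rd pattern was the small count at E11.5 (30) beside that at E12.5 (3416). A larger spread at E11.5 as the whole cause is argued against. The fit gives a probe set the same standard error for the sex difference at both days, as 0.59 for Fgf9 and 0.38 for Sox9. A larger spread at E11.5 therefore could not lower the E11.5 count through a larger standard error at that day. It also leaves the size of differences. Yet the median E11.5 difference of the 3416 probe sets, signed as at E12.5, was 0.11 against 1.39, a ratio of 0.08. Choosing these probe sets by their E12.5 call raises the 1.39 by itself, by an amount that was not measured. At E11.5 62.2% of them had the sign of E12.5. With the covariate for the difference between pools that crosses the sexes, the E11.5 count was still small, at 38. That covariate was built from the same arrays and describes only this difference, so other differences between pools remain in the fit. The value therefore cannot decide whether differences between pools kept the E11.5 count small. Measured by group, the spread was larger at E11.5 (residual SD 0.45 and 0.422 against 0.331 and 0.357), but the fit pools it over both days. Of the 3416 probe sets 747 passed the interaction test. For those 747 the sex difference thus changed between the days. For the other probe sets a later onset was not shown and stays open. Embryos of a pool differing in exact age may also play a part, which was not tested.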

How the results depend on the processing

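The alternatives were planned except the covariate for the difference between E11.5 pools, which was chosen after seeing the data; the cause of each change was not tested unless stated. The offset of 16 was not run because the values are already logarithms. The counts for sex at E11.5, sex at E12.5, day in XX, day in XY and interaction (30, 3416, 1378, 2726 and 774) stayed within 1.5 times under the brighter probe sets, both scalings, the mean-variance trend and the 2-fold minimum, with these exceptions elsewhere. Array quality weights gave 5794 for sex at E12.5, 2405 for day in XX and 539 shared stage changes. The compared arrays alone gave 12 for sex at E11.5 and 624 for day in XX, in fits with fewer samples. With 1 probe set per gene, which tests fewer, the counts were 12 for sex at E11.5, 1430 for day in XY (924 higher and 506 lower), and 9 and 153 for the overlaps of sex differences and of stage changes. The covariate gave 164 for day in XX, 499 for day in XY and 26 shared stage changes; the covariate was also lower on all 6 E12.5 arrays than on each E11.5 array, so it takes up part of the day itself. It also ended the calls of Mmd2 and Nudt19 at E11.5 and of Nusap1 at E12.5. The lists past the threshold in the day in XX fell from 11 to 6 with the brighter probe sets, and with an estimated correlation numbered 1, 2, 0, 3 and 2. Leaving out each array gave 23 to 57, 2054 to 3765, 183 to 1945, 1277 to 3077 and 403 to 1273 calls, 16 to 43 and 43 to 435 shared calls, and 8 to 11, 10 to 12, 8 to 12, 10 to 12 and 8 to 11 lists. The endothelial list in XX over the day ran from -0.95 to 0.20 around -0.51 and turned positive (0.20; adjusted p = 0.95) without XX E11.5 pool 2.

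Besides those named beside their results, list calls ended without these arrays. At E11.5 X-inactivation RNAs lost theirs without XX E11.5 pool 3, X-linked escape genes without 3 arrays (XX E11.5 pools 2 and 3, XY E11.5 pool 2) and FGF genes without 7 (XX E11.5 pools 1 and 3, XY E11.5 pools 1 and 3, all 3 XY E12.5 pools). At E12.5 macrophage markers lost theirs without 6 (XX E11.5 pool 1, XY E11.5 pool 2, XX E12.5 pools 1 and 2, XY E12.5 pools 2 and 3), mesonephric markers without 5 (XY E11.5 pools 1 and 2, XX E12.5 pool 2, XY E12.5 pools 1 and 3) and ribosomal proteins without XY E12.5 pool 1. Over the day in XX the Sertoli list lost its call without XX E11.5 pool 1 and pool 3, macrophage markers without XX E11.5 pool 1 and pool 2, ribosomal proteins without XX E11.5 pool 1 and cholesterol genes without 3 (XX E11.5 pool 2, XY E11.5 pool 1, XX E12.5 pool 1). In XY glycolysis lost its call without XY E12.5 pool 1 and immediate early genes without XY E11.5 pool 2. In the interaction immediate early genes lost theirs without XX E11.5 pool 3 and ribosomal proteins without 5 (XX E11.5 pool 1, XY E11.5 pools 2 and 3, XX E12.5 pool 3, XY E12.5 pool 1). Over the genes that the rule named, 439 results with 1 array left out were weaker, 104 stronger and 7905 the same. The lowest adjusted p of the X-linked genes under any alternative was 0.12. The brightest probe sets of Xist and Eif2s3y separated the sexes by 4.94 and 6.84, while 1 other probe set of each overlapped between the sexes.

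Pool numbers did not pair the samples: of 18 same-numbered pairs 4 had deviations correlated over 0.1 (-0.398 to 0.235), and 5 of 12 arrays correlated best with their own number. With the pool number as a block the shared stage changes numbered 314 and the shared sex differences 22. Signal over background limits the dim genes: Usp9y and Zfy2 could not be told from background in XY arrays.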

Other observations

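The lists in this part were tested after their first genes had been seen. Erbb3 and Sox10 had been seen before the glial list, and Gabra4 and Slitrk1 before the synaptic list. These genes were kept in the lists, so they count towards the list p-values, which are no independent test. Genes best known from glia and myelin were higher in XY at E12.5, 6 of 18 with 1 lower: Erbb3, Sox10, Mbp, Cnp, Dusp15 and Ttyh1 were higher and Pmp22 lower. Sox10 also belongs to the Sertoli list. As a list (median difference 0.19, mean 0.62) they passed with the preset correlation (adjusted p = 0.0033) and not with an estimated one (adjusted p = 0.15). A shared change of this class therefore stays open. Genes of neurotransmitter receptors and synaptic adhesion were lower in XY at E12.5 for 4 of 22, Gabra4, Gabrb1, Slitrk1 and Cntn5 (adjusted p = 0.021, and 0.15 with an estimated correlation). The median difference of that list was -0.08 and its mean -0.89, so most of its genes differed little.

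Cela3b, a pancreatic elastase gene, rose over the day at 3 of its 4 probe sets in XX and at all 4 in XY, by 2.69 and 3.53 at 1 of them (adjusted p = 0.021 and 0.0024), while pancreatic acinar genes as a list did not pass in XY (adjusted p = 0.54, and 0.75 with an estimated correlation). Phgdh was higher in XY at E11.5, and the list of serine synthesis and amino acid response genes did not pass there (adjusted p = 0.066, and 0.22 with an estimated correlation). Abcb1a read 3.79 in XX and 9.10 in XY at E11.5, and 3.75 and 4.17 at E12.5, so that its sex difference was called on the earlier day and not on the later one.

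Of the 6 E11.5 arrays 4 correlated best with an array of the other sex, XX pool 1 and XY pool 2 with each other (r = 0.98 across probe sets, which are not independent replicates) and XX pool 3 and XY pool 1 with each other (0.977). XX pool 2 correlated best with XX pool 1 (0.963) and XY pool 3 with XY pool 2 (0.962). The 365 probe sets higher in XX pool 3 and XY pools 1 and 3 covered 219 named genes, of which 201 had another probe set with a group mean of at least 8; the selected ones differed by a median of 1.77 and the others by 0.14. Choosing probe sets by this difference raises the 1.77 by itself. Over the day their median change was -1.10 in XX and -1.65 in XY, and 9 and 59 of them were called lower. Their choice as high in XX pool 3 and XY pools 1 and 3 raises the E11.5 means, more so in XY. A fall to E12.5 that is larger in XY therefore follows in part from the choice, by an amount that was not measured.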
